A study of Mus musculus with 6 samples.

How the data were processed

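RNA from mouse heart tissue was sequenced in 6 libraries, which the labels put in 3 groups of 2. Control mice ate regular chow and received no vector, per the labels. The other groups held C57BL/6 mice made diabetic at 12 weeks of age by a diet with 60% of calories from fat and a single streptozotocin injection of 75 mg/kg, per the labels' protocols. Streptozotocin is a toxin of pancreatic beta cells. Type 2 diabetes (T2D) was defined 20 weeks after the diet began. An adeno-associated virus (AAV) was injected into the jugular vein 16 to 18 weeks after streptozotocin, and experiments followed 4 weeks after the virus, at 5 to 6 months from induction. The virus was empty in one group and encoded a FLAG-tagged dominant negative MCUb, a subunit of the mitochondrial calcium uniporter, in the other, and these are called T2D empty vector and T2D dnMCUb. The series description speaks of MCUb where the sample labels name dnMCUb, and the sample labels were followed. The control group differed from both in diet, streptozotocin and vector together. The labels do not say whether the libraries of a group came from separate animals, so p-values measure the spread between these libraries.

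Libraries were prepared from total RNA after removal of ribosomal RNA with a stranded Illumina kit, per the labels' protocols. The submitters' processing notes name bcl2fastq 2.20.0.422, STAR 2.5.2a and DESeq2 as tools and GRCm38, mm10 and hg38 as builds, without their roles. The counting program, its strand setting and any filter are not given in the sources used here. A single table was used, with 1 row per gene. Its 6 value columns hold regularized log (rlog) values, which the authors deposited on the log2 scale. The rlog transformation scales libraries and draws each value towards its gene's mean, most strongly for low counts. The authors' deposited table also gives a log2 fold change, a p-value and an adjusted p-value for each of 3 comparisons. No counts were in the table, so the depth of each library is unknown and no interval for counting error is given. All 6 value columns carried a sample label, and 0 were left unused.

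The table has 54352 rows, of which 22778 were listed at 0 in all 6 libraries and 31574 varied between libraries. The rlog values ran from -2.09 to 22.07. Transcript identifiers of 53565 rows were found in GENCODE release M21, which is built on GRCm38, all 53565 at the same coordinates, and coordinates are printed as the table gives them. Symbols of 26 genes had been turned into dates and were restored by Ensembl identifier. The authors' log2 folds were set against the rlog means to learn their direction. Among genes with an authors' adjusted p under 0.05, the rlog difference was a median 0.577, 0.463 and 0.509 of the authors' log2 fold in the comparisons of T2D empty vector with control, T2D dnMCUb with T2D empty vector and T2D dnMCUb with control, so rlog differences are compressed.

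Differences of rlog were tested with limma 3.58.1 in R 4.3.3, with a mean-variance trend in the empirical Bayes step and Benjamini-Hochberg adjustment at 0.05, over the 13094 genes with a mean rlog of at least 5. All 6 libraries entered 1 fit with a term per group, which leaves 3 residual degrees of freedom, to which the prior added 4.6. Errors printed beside log2 differences are limma's standard errors, and errors beside group levels are SDs of 2 libraries. An exact two-sided permutation test of 2 libraries against 2 cannot give a p below 0.333, so none was used. Chance puts all libraries of 1 group on 1 side of the other for 33.33% of genes on average. Where genes move together, such shares and counts can lie far from their mean with no effect, and that spread was not estimated. Differences are always the group named first minus the other.

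Of 27 gene lists for pathways and 13 for cell types, 37 had at least 3 members among the genes tested. Lists for neutrophils, for lymphocytes and for lung, thymus and oesophagus had 1 tested member each and were not tested. Lists were tested with limma's camera at a preset correlation of 0.01 between genes, again with the correlation estimated from the data (with statmod 1.5.0 installed), and with fry, whose p tests whether a list's genes move one way on balance. Adjustment was over the 37 lists of a comparison. For list members, p-values were also adjusted over the list alone. The comparisons, tests, lists, alternatives and the rule for naming genes were chosen before the data were examined. For each comparison of main interest the rule takes up to 10 genes per direction among those past the threshold with groups apart, and otherwise all that pass plus up to 5 per direction with the smallest p that did not pass. For T2D dnMCUb against control it takes up to 5 per direction. It adds up to 4 members with the smallest p of each reported list, and fixed genes of the uniporter, fuel use, calcium handling and cardiac stress. Some genes named under this rule are not reported here. Genes named from the authors' deposited table, from fits other than the one described and as levels of single libraries were chosen after their values were seen, as were list members beyond the first 4.

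The gene test was tested on simulated data with the spread of these libraries, in which 50 genes were shifted at each size among 13094. A log2 shift of 0.25 was called in 78%, 78% and 60% of genes for the 3 comparisons in the order above. Shifts of 0.5, 1 and 2 were called in 100%, and every call had the right sign. These shares come from 1 draw per comparison with the same spread in each group, so they do not rank the comparisons. The real groups differed in residual SD, the SD over genes of a library's deviation from its group mean. It was 0.0379 in control, 0.0414 in T2D empty vector and 0.0675 in T2D dnMCUb. The shares therefore do not give the power in these libraries. Over 20 draws per comparison, 8.24%, 8.02% and 7.85% of calls were false, above the nominal 5%. A shift of 0.15 given to the interferon list was called by camera and by fry in each comparison. Among 36 unshifted lists camera called 0, 0 and 2 and fry 0, 0 and 1. Genes were simulated as independent of each other. In these data the estimated correlation between genes ran from -0.0165 in the interferon list to 0.966 in the red cell list. The counts therefore give no rate of false calls for lists whose genes move together.

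Alternatives covered the filter on low values, quantile normalization, centring on the library median, a fit to 2 groups only, the replicate number as a block, robust and trend-free variance estimates, other thresholds and the omission of each library in turn. The authors' own adjusted p and fits with the mean of the atrial or of the red cell list as a covariate were added as alternatives after the data were seen. Where a library is left out, its group keeps 1 library, which is assumed to vary like the others. Lists were then tested by camera at its preset correlation alone. Gene pairs with nearly identical copies, among them Hba-a1 and Hba-a2, Hbb-bs and Hbb-bt, Hspa1a and Hspa1b, Ifit3 and Ifit3b, and Acot1 and Acot2, are uncertain as single genes, since the counting could split their reads.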

Results

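Gene expression was measured by RNA sequencing in 6 mouse heart libraries, 2 from control mice, 2 from diabetic mice given an empty viral vector and 2 from diabetic mice given a vector for a dominant negative MCUb (dnMCUb). Values are rlog values on the log2 scale, and 13094 genes were tested. Depth is unknown for every library, since the values used are not counts. Of the variance between libraries, 46.69% lay on a first component on which library 1 labelled dnMCUb stood at 10.8 and the other libraries between -4.42 and 2.69. The SD over genes of a library's deviation from its group mean was 0.0379 in control, 0.0414 in T2D empty vector and 0.0675 in T2D dnMCUb. The differences between the 2 libraries of a group had SDs of 0.0758, 0.0829 and 0.1351 in that order.

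Mcub (ENSMUSG00000027994.14, minus strand of chromosome 3 from 129914960 to 129970206, GRCm38), the gene the vector encodes in mutated form, was measured first as a check of the labels. Its rlog was 5.42 and 5.47 in control, 5.48 and 5.46 in T2D empty vector, and 5.62 and 5.47 in T2D dnMCUb. The group levels were 5.45 ± 0.03, 5.47 ± 0.02 and 5.55 ± 0.11 (SD, n = 2). Mcub was higher in T2D dnMCUb than in T2D empty vector by 0.08 (SE 0.05; limma, adjusted p = 0.888) and than in control by 0.10 (adjusted p = 0.481). Without library 1 labelled dnMCUb the difference from T2D empty vector was 0.000315, and without library 2 it was 0.155 (SE 0.03, adjusted p = 0.114). In the authors' deposited table the log2 fold of Mcub between those groups was 0.65, with an adjusted p of 1. No rise of Mcub passed in these tests, and the sources used here do not say whether reads of the vector's coding sequence were counted under that gene. This gene does not tell whether the label is right, so the libraries are called "labelled dnMCUb" and every direction involving them rests on the label. Male-specific Ddx3y lay between 11.46 and 11.57 and Xist between 0.80 and 0.81 in all 6 libraries.

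**Figure D1:**
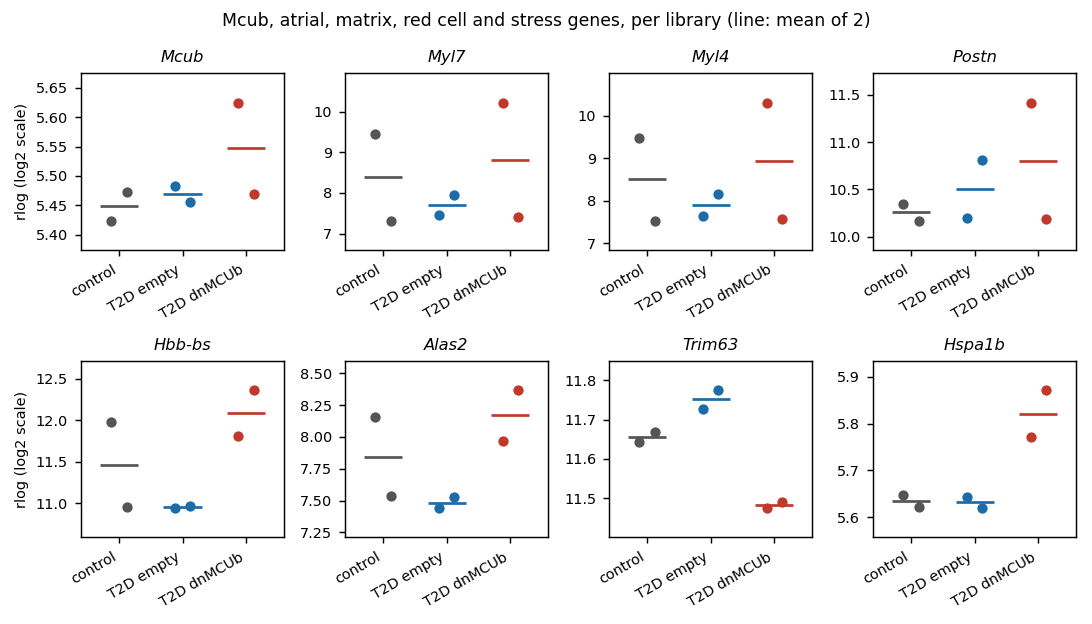
Levels of Mcub, atrial myosin light chains (Myl7, Myl4), the matrix gene Postn, red cell genes (Hbb-bs, Alas2), Trim63 and Hspa1b as rlog (log2 scale) in each library, with points for single libraries and lines for group means. Mcub lay between 5.42 and 5.62, and Myl7 reached 10.22 in library 1 labelled dnMCUb and 9.45 in control library 1 against 7.32 to 7.94 in the others.

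Control hearts were compared with T2D empty vector hearts to ask what diabetes, together with an empty vector, did to cardiac gene expression. Target genes of PPAR alpha, a nuclear receptor that senses fatty acids, rose in T2D empty vector: 21 of 22 were higher, with a median log2 difference of 0.15 (limma's camera, adjusted p = 6.44e-11; adjusted p = 0.731 with an estimated correlation). Pdk4, a kinase that blocks pyruvate dehydrogenase, stood at 12.49 ± 0.26 in control and 13.71 ± 0.0017 in T2D empty vector (SD, n = 2), a difference of 1.22 (SE 0.17). The acyl-CoA thioesterase genes Acot1 and Acot2 were higher by 0.53 (SE 0.09) and 0.56 (SE 0.10). These 3 genes passed when adjusted over the list alone (adjusted p = 0.00274 for Pdk4), and none passed over all genes tested. Levels of Ppara itself (difference -0.05, adjusted p = 0.906) and of Ppargc1a (0.01, adjusted p = 0.988) differed by less than their standard errors of 0.065 and 0.097.

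Other fuel lists moved in T2D empty vector in both directions. The fatty acid list shares many genes with the PPAR alpha list, Acot1 and Acot2 among them, so these calls are not separate findings. Fatty acid uptake and oxidation rose (28 of 33 genes higher, median 0.11, camera adjusted p = 3e-06; adjusted p = 0.81 with an estimated correlation). Of its members 2, Acot1 and Acot2, passed when adjusted over the list alone. Ketone and branched chain amino acid oxidation fell (16 of 18 lower, median -0.08, adjusted p = 0.00357; adjusted p = 0.81 with an estimated correlation). When adjusted over that list alone, 1 member passed, and it rose against the direction of the list. Oxct1, which acts on acetoacetate in ketone body breakdown, was at -0.23 (SE 0.07) and did not pass. Glucose uptake and glycolysis fell (19 of 23 lower, median -0.06, adjusted p = 0.00122; adjusted p = 0.731 with an estimated correlation). Hexokinase gene Hk1 (-0.27) and the basal glucose transporter gene Slc2a1 (-0.17, SE 0.04) fell when adjusted over the list alone, while the insulin-responsive transporter gene Slc2a4 was at -0.18 (SE 0.08) and did not pass. Nuclear genes of the respiratory chain fell (45 of 50 lower, median -0.05, adjusted p = 0.00174; adjusted p = 0.81 with an estimated correlation) with no member passing over the list alone. The insulin signalling list was not called (adjusted p = 0.932), and its median of 0.02 and mean of -0.01 differ in sign. Its member Irs1, the insulin receptor substrate, fell when adjusted over the list alone (-0.31, SE 0.05, adjusted p = 0.00546). In lipid synthesis and storage, also not called (0.371, with a median of -0.01 and a mean of 0.04), Me1, Scd4, Gpam, Lipe and Insig1 rose among the members that passed over the list alone, not all of which rose. Without T2D empty vector library 2 the calls for ketone oxidation (median -0.05), glycolysis (-0.05) and nuclear respiratory chain genes (-0.02) were lost. Without control library 1 those for ketone oxidation (-0.07) and the respiratory chain (-0.03) were lost. Still called, ketone oxidation was at -0.13, glycolysis at -0.11 and the respiratory chain at -0.09 without T2D empty vector library 1, and the respiratory chain at -0.10 and fatty acid oxidation at 0.07 without control library 2.

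Contractile genes were lower in T2D empty vector. The sarcomere list fell (19 of 22 lower, median -0.11, camera adjusted p = 0.00666; adjusted p = 0.81 with an estimated correlation). Tnnc1 was at -0.21 and Mybpc3 at -0.22, neither passing. Calcium handling fell (16 of 20 lower, median -0.06, adjusted p = 0.00666; adjusted p = 0.731 with an estimated correlation). Asph was at -0.15 and Camk2d at -0.16, while the calcium pump gene Atp2a2 (0.00) and its inhibitor Pln (-0.06) were within their standard errors of 0.13. The natriuretic peptide genes Nppa and Nppb were lower, by a difference of -0.94 (SE 0.27, adjusted p = 0.706) and -0.50 (SE 0.14, adjusted p = 0.684), and did not pass. Nppa is also on the atrial myocyte list, whose median was 0.10 without control library 1. Myosin genes Myh6 (-0.13, SE 0.18) and Myh7 (-0.20, SE 0.21) did not differ beyond their errors. The fetal and stress list was not called (adjusted p = 0.582, median 0.01 and mean -0.07). Ion channel genes were not called (adjusted p = 0.227), but Scn4b, a sodium channel subunit, rose when adjusted over the list alone (0.57, SE 0.10). The uniporter complex did not move as a list (median -0.01 over 16 genes, adjusted p = 0.924), with Mcu at -0.06 and Micu2, Smdt1 and Mcur1 between -0.04 and 0.00. Without T2D empty vector library 1 the calls for sarcomere (median -0.10) and calcium handling (-0.07) were lost, and without control library 1 that for the sarcomere (-0.07).

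Clock, immune and stress genes also differed. The circadian clock list rose (13 of 19 higher, median 0.16, camera adjusted p = 0.00666; adjusted p = 0.731 with an estimated correlation). Over the list alone 5 genes rose, among them Dbp (0.46), Bhlhe41 (0.21) and Nr1d2 (0.25), and 3 fell, among them Arntl (-0.38) and Nfil3 (-0.13). Interferon response genes rose (32 of 34 higher, median 0.09, adjusted p = 1.75e-16; adjusted p = 0.0788 with an estimated correlation; fry adjusted p = 0.0327). Groups stood apart in 27 of the 34, where chance gives 33.33% of genes. When adjusted over the list alone 8 rose, led by Rsad2 (0.25, SE 0.04), Rtp4 (0.17), Ifit1 (0.23) and Gbp2 (0.16). Immediate early genes (median 0.09, camera adjusted p = 0.000123), inflammatory cytokines and complement (0.04, 0.00259), cell cycle (0.03, 0.00172) and autophagy and atrophy (0.02, 0.0468) rose. Each had an adjusted p of 0.731 with an estimated correlation. Oxidative stress genes rose (median 0.05, adjusted p = 0.00947; adjusted p = 0.81 with an estimated correlation). Cytosolic ribosomal proteins fell (36 of 40 lower, median -0.06, adjusted p = 2.46e-05; adjusted p = 0.731 with an estimated correlation) and so did heat shock genes (median -0.06, adjusted p = 0.0468; adjusted p = 0.81 with an estimated correlation). Macrophage markers were not called (median 0.03, adjusted p = 0.0806), although Ccr2 rose when adjusted over the list alone (0.30, SE 0.06). Without T2D empty vector library 1 the calls for inflammatory (median 0.07), cell cycle (0.02), autophagy (0.01), oxidative stress (0.0024) and heat shock genes (-0.05) were lost. Without control library 2 those for autophagy (0.03), oxidative stress (0.02) and heat shock (-0.03) were lost, as were autophagy without control library 1 (0.03) and heat shock without T2D empty vector library 2 (-0.04). Immediate early genes stayed called at a median of 0.05 without control library 1 or T2D empty vector library 1 and of 0.14 without control library 2. Inflammatory genes did so at 0.08 without control library 1, and autophagy (0.05) and oxidative stress genes (0.08) without T2D empty vector library 2.

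Markers of other tissues and cells moved with this comparison. Atrial myocyte genes fell (median -0.18, camera adjusted p = 0.0274; adjusted p = 0.81 with an estimated correlation) and red cell genes fell (median -0.37, adjusted p = 0.00118; adjusted p = 0.731 with an estimated correlation). Both rested on control library 1, with Myl7 at 9.45 against 7.32 in control library 2 and Hbb-bs at 11.98 against 10.96, and without it the medians were 0.10 and -0.02. The atrial call was also lost without T2D empty vector library 1 (-0.20). Atrial genes stayed called at -0.41 without T2D empty vector library 2, and at -0.30 without control library 2, as red cell genes did at -0.73. Extracellular matrix genes rose (33 of 39 higher, median 0.11, adjusted p = 0.00174; adjusted p = 0.81 with an estimated correlation), but groups stood apart in 5 of the 39 (33.33% by chance), and the median was -0.05 without T2D empty vector library 2 and 0.24, still called, without library 1. Adipocyte genes rose (median 0.12, adjusted p = 0.0274; adjusted p = 0.731 with an estimated correlation), with Lipe passing over the list alone, and were not called without control library 2 (0.14) or T2D empty vector library 1 (0.07). Lists for fibroblasts (median 0.08), endothelial cells (0.05), smooth muscle (-0.02), conduction system (-0.01), epicardium (0.03) and skeletal muscle (0.03, with a test downwards) were not called. Antigen presentation (0.10), mitochondrial genes of the respiratory chain (0.02), mitochondrial biogenesis (-0.03), pyruvate dehydrogenase and TCA cycle (-0.06) and the integrated stress response (0.01, mean -0.01) were not called.

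Over all genes limma called 0 between T2D empty vector and control (smallest adjusted p = 0.312) in the fit whose spread is shared with T2D dnMCUb. At an unadjusted p under 0.05 it had 803 (427 higher, 376 lower) against 655 by chance. Groups stood apart for 42.38% of genes, where chance gives 33.33%. Both chance values are means, and neither excess is a test, since genes can move together with no effect. The genes with the smallest p that did not pass included Rhobtb1 (0.56, SE 0.07), Scn4b and Agrn (0.29) on the higher side, and Lrrc4b (-0.64, SE 0.08), Adcy1 (-0.34), Scgb1c1 (-0.29) and Krt222 (-0.27) on the lower. The authors' deposited table has 72 genes with an adjusted p under 0.05, 36 higher and 36 lower, and 597 at an unadjusted p under 0.05. Its higher genes were led by Acot2 (log2 fold 0.87, adjusted p = 1.22e-16), Rhobtb1 (0.90), Gpam (0.62), Scd4 (1.18) and Pdk4 (1.79), per the authors' deposited table. In the authors' deposited table the lower ones were led by Abat (-1.47, adjusted p = 1.29e-17), Tuba4a (-0.72), Lrrc4b (-1.80), Ndrg4 (-0.79) and Myom2 (-0.57). With only the control and T2D empty vector libraries in the limma fit, or without either library labelled dnMCUb, 30 genes were called, and all 30 of the fit to those groups were among the 72. Without control library 2 the count was 1. Of 20 list calls, 6 held by camera at its preset correlation when each library was left out in turn. They were PPAR alpha targets, fatty acid oxidation, clock, immediate early, interferon and ribosomal protein genes, of which the first 2 lists share genes. With an estimated correlation 0 lists were called with all libraries, and fry called only the interferon list.

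**Figure D2:**
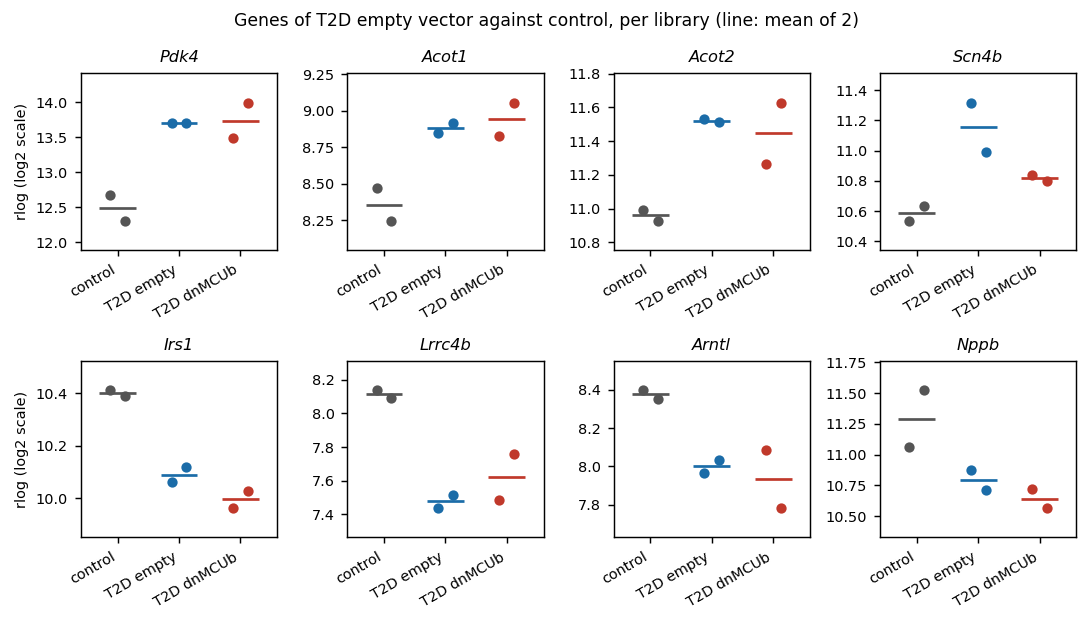
Levels of 8 genes named in the comparison of T2D empty vector with control hearts, none of which passed over all genes in limma, as rlog (log2 scale), with points for single libraries and lines for group means of 2. Pdk4 stood at 12.31 and 12.67 in control and at 13.49 to 13.99 in the diabetic libraries, while Nppb was at 11.06 and 11.53 in control and 10.57 to 10.87 in the others.

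Diabetic hearts with the dnMCUb label were compared with diabetic hearts given empty vector to ask what the vector's cargo changed. Interferon response genes rose: 33 of 34 were higher in the libraries labelled dnMCUb, with a median of 0.14 (limma's camera, adjusted p = 5.01e-26; adjusted p = 0.0401 with an estimated correlation; fry adjusted p = 0.0153). Irf7, a transcription factor that drives interferon production, stood at 7.88 ± 0.0095 in T2D empty vector and 8.37 ± 0.12 in T2D dnMCUb (SD, n = 2), a difference of 0.49 (SE 0.06). Ifi44 (0.24, SE 0.03), Ifit3b (0.17), Ifit1 (0.32) and the guanylate binding protein gene Gbp3 (0.20) followed. Groups stood apart in 30 genes with the labelled libraries higher and in 1 with them lower, against 33.33% of genes by chance. When adjusted over the list alone 21 rose and 1 fell, while none passed over all genes tested. The mean of the list relative to its average was 0.13 and 0.13 in the libraries labelled dnMCUb, -0.02 and -0.01 in T2D empty vector and -0.11 and -0.13 in control. Genes for antigen presentation by MHC class II rose (7 of 7 higher, median 0.13, adjusted p = 0.000939; adjusted p = 0.685 with an estimated correlation). Inflammatory and complement genes rose as well (median 0.09, adjusted p = 0.00194; adjusted p = 0.685 with an estimated correlation), with C1qb at 0.24 and Ccl11 at 0.18 not passing. Without T2D empty vector library 2 the calls for antigen presentation (median 0.06) and inflammatory genes (0.06) were lost, as were the former without library 2 labelled dnMCUb (0.04) and the latter without library 1 (0.02). Still called, antigen presentation was at 0.22 without T2D empty vector library 1 or library 1 labelled dnMCUb, and inflammatory genes at 0.14 without library 2 labelled dnMCUb.

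Beside these immune genes, macrophage markers rose (15 of 16 higher, median 0.08, camera adjusted p = 1.97e-06; adjusted p = 0.685 with an estimated correlation). Lyve1 (0.32), C1qb, Cd163 (0.23), Cd14 (0.11) and C1qc (0.15) passed when adjusted over the list alone. The macrophage median was 0.04 without library 1 labelled dnMCUb and 0.14 without library 2, called in both cases. Red cell genes rose with them (7 of 7 higher, median 0.77, adjusted p = 4.47e-09; adjusted p = 0.662 with an estimated correlation). All 7 passed over the list alone, with Hbb-bs higher by 1.13 (SE 0.30), Hba-a1 by 0.92, Hba-a2 by 0.88 and Alas2, an enzyme of heme synthesis, by 0.69. Hbb-bs was at 11.80 and 12.36 in the libraries labelled dnMCUb, 10.94 and 10.97 in T2D empty vector, and 11.98 and 10.96 in control.

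Protein synthesis and folding genes rose in the libraries labelled dnMCUb. Cytosolic ribosomal protein genes rose (37 of 40 higher, median 0.10, camera adjusted p = 3.52e-14; adjusted p = 0.662 with an estimated correlation), with Rpl19 at 0.16 and Rpl13a at 0.17, none passing over the list alone. Heat shock genes rose (11 of 16 higher, median 0.13, adjusted p = 0.000295; adjusted p = 0.685 with an estimated correlation). The chaperone genes Hspa1a (0.19), Hspa1b (0.19), Dnaja1 (0.28, SE 0.07) and Hsp90aa1 (0.23) passed over the list alone. The heat shock list mean was 0.13 in library 2 labelled dnMCUb and -0.04 in library 1, and without library 2 the median was 0.03 and the call was lost. The integrated stress response and protein folding list rose (median 0.04, adjusted p = 0.0205; adjusted p = 0.662 with an estimated correlation), with Calr at 0.22 and Pdia4 at 0.17 not passing. It was not called without T2D empty vector library 1 (median 0.05) or library 2 labelled dnMCUb (0.06). Immediate early genes rose (18 of 18 higher, median 0.11, adjusted p = 2.38e-06; adjusted p = 0.662 with an estimated correlation), led by Ier2 (0.14), Egr1 (0.17) and Dusp1 (0.33), none passing. Without library 2 labelled dnMCUb the immediate early (0.05) and ribosomal (0.06) medians were smaller and still called, and without library 1 those of heat shock (0.23) and the integrated stress response (0.07) were larger. Autophagy and atrophy genes fell (16 of 20 lower, median -0.05, adjusted p = 0.00355; adjusted p = 0.685 with an estimated correlation). Trim63, which encodes the muscle ubiquitin ligase MuRF1, fell when adjusted over the list alone (-0.27, SE 0.05, adjusted p = 0.0149), and Fbxo32, which encodes atrogin-1, was at -0.25 (SE 0.07) and did not pass. Without T2D empty vector library 1 the atrophy list was not called (median -0.02).

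Fuel and contractile genes were lower as lists and in no single gene. Ketone and branched chain amino acid oxidation fell (16 of 18 lower, median -0.07, camera adjusted p = 0.00141; adjusted p = 0.685 with an estimated correlation), with Oxct1 at -0.21 (SE 0.07) and Bdh1 at -0.82 (SE 0.29). Pyruvate dehydrogenase and TCA cycle fell (30 of 32 lower, median -0.06, adjusted p = 0.00141; adjusted p = 0.753 with an estimated correlation). Glycolysis fell (median -0.07, adjusted p = 0.00623; adjusted p = 0.685 with an estimated correlation). Fatty acid oxidation fell (median -0.05, adjusted p = 0.0297; adjusted p = 0.831 with an estimated correlation), and so did the sarcomere (median -0.07, adjusted p = 0.0363; adjusted p = 0.804 with an estimated correlation). Without library 1 labelled dnMCUb no list of this group fell: the medians were 0.03 for the TCA cycle, 0.0006 for glycolysis and -0.02 for ketone oxidation, and fatty acid oxidation (0.08) and the sarcomere (0.04) were called upwards. All 5 calls were also lost without T2D empty vector library 1 (medians -0.03, -0.04, -0.04, -0.02 and -0.06 in that order), and the sarcomere without either control library (-0.07) or T2D empty vector library 2 (-0.07). Without library 2 labelled dnMCUb all 5 were called, with medians of -0.16, -0.13, -0.15, -0.17 and -0.15 in the same order, and without T2D empty vector library 2 the TCA cycle was at -0.11, ketone oxidation at -0.11 and fatty acid oxidation at -0.08. PPAR alpha targets were not called (adjusted p = 0.952, median -0.01 and mean 0.02), and Pdk4 differed by 0.03 (SE 0.17). Slc2a4 was at -0.17 (SE 0.08) and Slc2a1 at -0.08 (SE 0.04), neither passing. Ppara was at -0.04, Ppargc1a at -0.06, Atp2a2 at -0.13, Pln at -0.05, Myh6 at -0.06, Myh7 at 0.21, Nppa at 0.64 (SE 0.27) and Nppb at -0.15, none passing. Nppa is also on the atrial myocyte list, whose median was -0.06 without library 1 labelled dnMCUb. Calcium handling (median -0.04, adjusted p = 0.127) and the uniporter complex (median -0.02, adjusted p = 0.446) were not called, with Mcu at 0.01, Micu2 at -0.04, Smdt1 at -0.01 and Mcur1 at -0.06.

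Markers of other tissue parts moved here as well. Atrial myocyte genes rose (median 0.49, camera adjusted p = 0.0141; adjusted p = 0.685 with an estimated correlation), with Myl7 at 10.22 in library 1 labelled dnMCUb and 7.40 in library 2, and the median was -0.06 without library 1. Fibroblast genes rose (median 0.12, adjusted p = 0.00589; adjusted p = 0.696 with an estimated correlation), but the median was -0.08 without the same library, then called downwards, and -0.0098 without T2D empty vector library 1. Conduction system genes (median 0.06, adjusted p = 0.0238), endothelial genes (0.06, 0.0197) and epicardial genes (0.06, 0.0163) rose, each with an adjusted p of 0.685 with an estimated correlation. Without library 1 labelled dnMCUb the conduction (0.0054) and endothelial (0.02) calls were lost, and without its library 2 the epicardial one (0.03). Without T2D empty vector library 1 the conduction call (0.05) was lost, and without library 2 the endothelial (0.02) and epicardial (0.01) calls. Medians still called were 1.06 for atrial, 0.14 for conduction and 0.33 for fibroblast genes without library 2 labelled dnMCUb, and 0.11 for epicardial genes without library 1. They were 0.27 for atrial and 0.10 for epicardial genes without T2D empty vector library 1, and 0.27 for fibroblast genes without library 2. Matrix genes (median 0.07, adjusted p = 0.125), adipocytes (0.05), smooth muscle (-0.0021, mean 0.05), skeletal muscle (-0.07), clock (0.01) and insulin signalling genes (-0.02) were not called. Nor were oxidative stress (-0.02), ion channels (-0.0042), lipid synthesis (-0.01, mean 0.0007), cell cycle (-0.0032), fetal and stress genes (-0.06), mitochondrial biogenesis (-0.04), and nuclear (-0.03) and mitochondrial (-0.02, mean 0.0003) respiratory chain genes.

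Over all genes limma called 0 between T2D dnMCUb and T2D empty vector (smallest adjusted p = 0.646), with 739 at an unadjusted p under 0.05 (408 higher, 331 lower) against 655 by chance. Groups stood apart for 32.16% of genes against 33.33% by chance. Besides the interferon genes, those with the smallest p were Zbtb16, a zinc finger transcription factor (0.57, SE 0.09), and on the lower side Trim63, Ano5 (-0.28), Cpeb3 (-0.24), Scn4a (-0.30) and Synj2 (-0.21), none passing. The authors' deposited table has 9 genes with an adjusted p under 0.05, all higher, and 259 at an unadjusted p under 0.05. These 9 in the authors' deposited table were Hba-a2 (log2 fold 1.89, adjusted p = 7.63e-11), Hba-a1 (1.74), Hbb-bt (1.66), Hbb-bs (1.74), Alas2 (1.98), Tent5c (1.38), Irf7 (1.27, adjusted p = 9.16e-05), Zbtb16 (0.99, adjusted p = 9.24e-05) and the predicted gene Gm10718 (4.66). By camera at its preset correlation, 5 of 20 list calls held when each library was left out in turn (interferon, immediate early, ribosomal, macrophage and red cell genes). With an estimated correlation, and by fry, only the interferon list was called with all libraries.

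**Figure D3:**
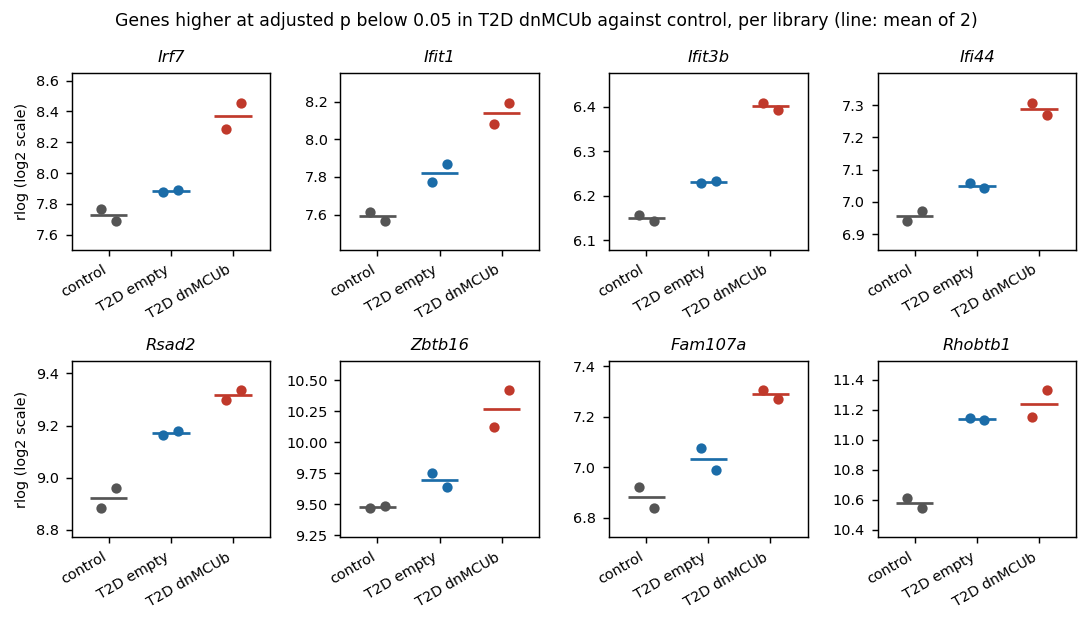
Levels of 8 genes that rose in T2D dnMCUb against control as rlog (log2 scale), with points for single libraries and lines for group means of 2. Irf7 lay at 7.69 and 7.77 in control, 7.88 and 7.89 in T2D empty vector and 8.29 and 8.46 in the libraries labelled dnMCUb.

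Diabetic hearts with the dnMCUb label were also compared with control hearts, a contrast that joins diabetes, vector and cargo. Of 13094 genes 9 passed in limma, all at an adjusted p of 0.04999, and 5 of the 8 that rose are interferon response genes. Irf7 (ENSMUSG00000025498.15, chromosome 7) rose from 7.73 ± 0.055 to 8.37 ± 0.12 (SD, n = 2), by 0.64 (SE 0.06), and Ifit1 (ENSMUSG00000034459.8, chromosome 19), an antiviral RNA-binding protein gene, by 0.55 (SE 0.05). Rsad2 (0.39), Ifi44 (0.33) and Ifit3b (0.25) rose too. Zbtb16 (ENSMUSG00000066687.5, chromosome 9) rose by 0.79 (SE 0.09), Rhobtb1 (ENSMUSG00000019944.14, chromosome 10) by 0.66 (SE 0.07) and Fam107a by 0.41 (SE 0.05). Irs1 (ENSMUSG00000055980.2, chromosome 1), the 1 gene that fell, was at 10.41 and 10.39 in control and at 9.96 and 10.03 in T2D dnMCUb, a difference of -0.41 (SE 0.05). On the lower side Epha4 (-0.44, adjusted p = 0.0574), Gnb3 (-0.29), Krt222 (-0.30), Lpin1 (-0.36) and Snn (-0.29) did not pass.

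Interferon response genes rose as a list (33 of 34 higher, median 0.25, camera adjusted p = 4.27e-34; adjusted p = 0.0268 with an estimated correlation; fry adjusted p = 0.00153), and 29 rose when adjusted over the list alone. Antigen presentation (7 of 7 higher, median 0.27, adjusted p = 8.23e-05) and inflammatory and complement genes (median 0.17, adjusted p = 7.67e-07) rose, each with an adjusted p of 0.529 with an estimated correlation. H2-Ab1 (0.28), Cd74 (0.28), C1qb (0.30) and Ccl6 (0.23) passed over the list alone. Macrophage markers rose beside them (16 of 16 higher, median 0.14, adjusted p = 1.53e-07; adjusted p = 0.529 with an estimated correlation), 6 over the list alone, among them Ccr2 (0.30) and Cd163 (0.26). Immediate early genes rose (18 of 18 higher, median 0.21, adjusted p = 2.53e-11; adjusted p = 0.357 with an estimated correlation), 12 over the list alone, among them Ier3 (0.24) and Egr1 (0.20). The clock list rose (median 0.15, adjusted p = 0.00147; adjusted p = 0.529 with an estimated correlation). Over the list alone 9 clock genes rose, among them Hlf (0.33), Dbp (0.46) and Per2 (0.51), and 2 fell, among them Arntl (-0.44). Cytosolic ribosomal proteins (median 0.04, adjusted p = 0.00748), the integrated stress response (0.05, 0.0341) and cell cycle genes (0.04, 0.00654) rose, with adjusted p-values of 0.653, 0.529 and 0.605 with an estimated correlation. Without library 2 labelled dnMCUb the clock (0.12), ribosomal (-0.0018) and integrated stress response (0.04) calls were lost, and without library 1 the cell cycle call (0.03). The integrated stress response call was also lost without control library 1 (0.02) and the ribosomal call without control library 2 (0.03). Still called without library 1 labelled dnMCUb were inflammatory (0.07), macrophage (0.08) and ribosomal genes (0.08), and without library 2 antigen presentation (0.15) and cell cycle genes (0.06). Without control library 1 the clock (0.10) and cell cycle (0.06) lists stayed called.

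Fuel lists split by direction again, with many genes shared by the PPAR alpha and fatty acid lists. PPAR alpha targets rose (19 of 22 higher, median 0.13, camera adjusted p = 1.57e-07; adjusted p = 0.621 with an estimated correlation). Their median was 0.03 without library 2 labelled dnMCUb and 0.26 without library 1, called in both cases. Over the list alone genes that rose included Pdk4 by 1.25 (SE 0.17), Acot1 by 0.58, Acot2 by 0.49 and Ucp2 by 0.24. Over all genes Pdk4 had an adjusted p of 0.0576. Fatty acid oxidation rose (median 0.07, adjusted p = 0.0176; adjusted p = 0.697 with an estimated correlation), with a median of -0.07 without library 2 labelled dnMCUb and 0.02, not called, without control library 2. Glycolysis fell (19 of 23 lower, median -0.14, adjusted p = 3.49e-06; adjusted p = 0.529 with an estimated correlation). Over the list alone 8 of its genes fell, among them Slc2a1 (-0.26), Hk2 (-0.34), Hk1 (-0.28) and Slc2a4 (-0.35, SE 0.08), while Pfkfb3 (0.21) rose. Ketone and branched chain amino acid oxidation fell (median -0.15, adjusted p = 3.49e-06; adjusted p = 0.621 with an estimated correlation), 7 genes over the list alone, among them Oxct1 (-0.45) and Dbt (-0.28), although not every member that passed fell. Pyruvate dehydrogenase and TCA cycle (median -0.11, adjusted p = 5.63e-05), nuclear respiratory chain (-0.10, 5.63e-05), mitochondrial biogenesis (-0.06, 0.00916) and sarcomere genes (-0.19, 8.23e-05) fell, each with an adjusted p of 0.653 with an estimated correlation. None of these 4 was called without library 1 labelled dnMCUb (medians -0.02, 0.0086, -0.0077 and -0.06). Calcium handling fell (median -0.12, adjusted p = 0.000522; adjusted p = 0.529 with an estimated correlation), with Camk2d at -0.21 not passing. Other medians that stayed called without library 1 labelled dnMCUb were -0.07 for calcium handling, -0.09 for glycolysis, -0.07 for ketone oxidation and 0.21 for fatty acid oxidation. Without library 2 they were -0.20 for calcium handling, -0.24 for glycolysis, -0.20 for the TCA cycle, -0.21 for the respiratory chain, -0.11 for mitochondrial biogenesis and -0.30 for the sarcomere, and without control library 1 -0.06 for the respiratory chain and 0.11 for fatty acid oxidation. Tnnc1 (-0.33) and Nppb (-0.65, SE 0.14) fell when adjusted over their lists alone. Nppa (-0.30), Myh6 (-0.20), Myh7 (0.01), Atp2a2 (-0.13), Pln (-0.10), Ppara (-0.09), Ppargc1a (-0.05), Mcu (-0.05), Micu2 (-0.05), Smdt1 (-0.01) and Mcur1 (-0.10) did not pass.

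Structural cell markers moved with the same contrast and with 1 library. Matrix genes (36 of 39 higher, median 0.16, camera adjusted p = 6.79e-05) and fibroblast genes (16 of 16 higher, median 0.20, adjusted p = 0.000154) rose, each with an adjusted p of 0.653 with an estimated correlation. The matrix gene Postn was at 11.42 in library 1 labelled dnMCUb and 10.19 in library 2, against 10.34 and 10.17 in control, and without library 1 the medians were -0.03 for matrix and -0.01 for fibroblast genes. Endothelial (median 0.08, adjusted p = 0.0083), epicardial (0.09, 0.00748), red cell (0.40, 0.00748) and adipocyte genes (0.19, 0.00283) rose, with adjusted p-values of 0.649, 0.621, 0.653 and 0.529 with an estimated correlation, in that order. Without control library 2 the red cell (median 0.04) and epicardial (0.04) calls were lost, and without library 2 labelled dnMCUb those medians were 0.17 and 0.06 and not called. The endothelial call was lost without control library 1 (0.03) and without library 1 labelled dnMCUb (0.04). Medians still called were 0.36 for matrix and 0.40 for fibroblast genes without library 2 labelled dnMCUb, and 0.63 for red cell genes without library 1. Without control library 1 red cell genes were at 0.76, and without control library 2 endothelial genes at 0.14. Atrial genes (median 0.14, adjusted p = 0.833), conduction (0.07), smooth muscle (-0.04, mean 0.03), skeletal muscle (-0.03) and uniporter genes (-0.05) were not called. Nor were mitochondrial respiratory chain (-0.0015, mean 0.0011), fetal and stress (-0.10), insulin signalling (-0.02), oxidative stress (0.02), heat shock (0.05), ion channel (-0.02), lipid synthesis (0.02) and autophagy genes (-0.02).

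At an unadjusted p under 0.05 limma had 1497 genes between T2D dnMCUb and control (771 higher, 726 lower) against 655 by chance, and groups stood apart for 42.87% of genes against 33.33%. Here too neither excess is a test. The authors' deposited table has 104 genes with an adjusted p under 0.05, 70 higher and 34 lower, and 766 at an unadjusted p under 0.05. Higher genes in the authors' deposited table were led by Zbtb16 (log2 fold 1.39, adjusted p = 1.54e-11), Irf7 (1.79), Rhobtb1 (1.06) and Ifit1 (1.66), and lower ones by Rrad (-0.72, adjusted p = 3.23e-06), Oxct1 (-0.64) and Nppb (-1.04). The limma count was 0 without control library 1 or either T2D empty vector library, 1 without control library 2, 89 without library 1 labelled dnMCUb and 743 without library 2, after which the group is a single library. Of 24 list calls, 10 held by camera at its preset correlation when each library was left out in turn. Among them were interferon, immediate early, PPAR alpha, glycolysis, calcium handling and macrophage genes. With an estimated correlation, and by fry, only the interferon list was called with all libraries.

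**Figure D4:**
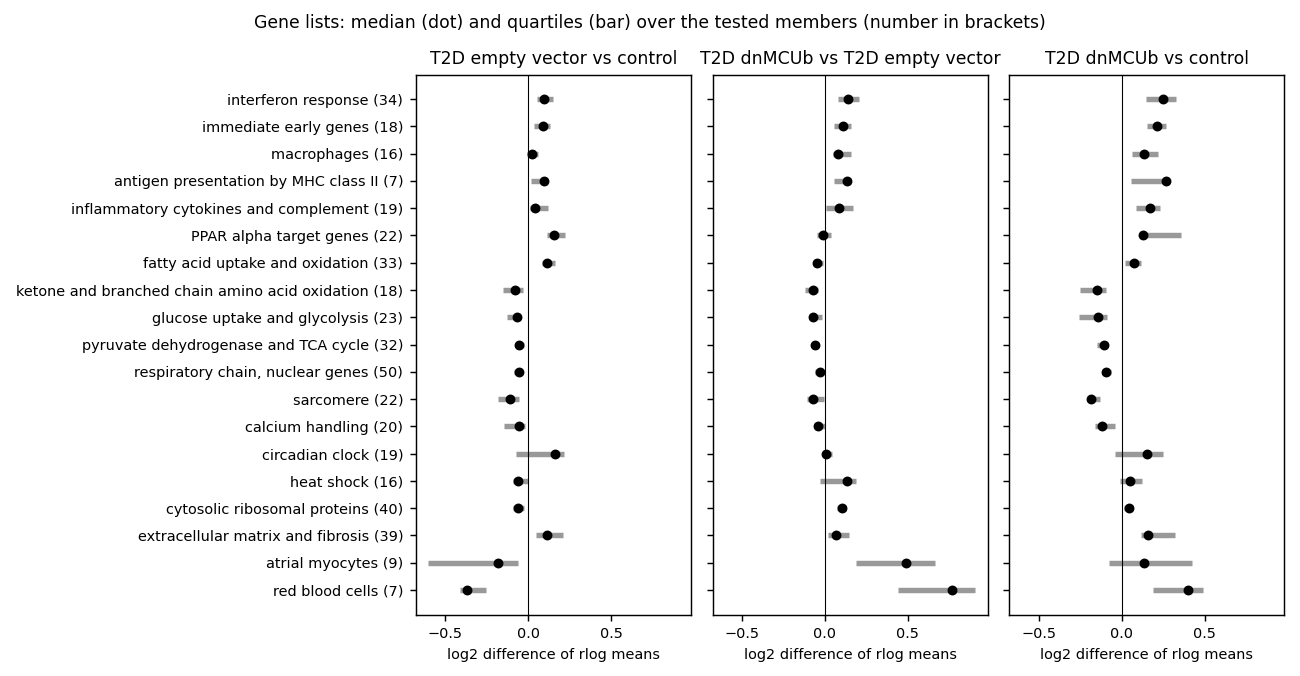
Median log2 difference of 19 gene lists in each of the 3 comparisons, with dots for medians and bars for quartiles over the genes of a list. The interferon list sits at 0.09, 0.14 and 0.25 and the PPAR alpha list at 0.15, -0.01 and 0.13.

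Whether the label's effect opposed that of diabetes was asked by setting the difference between T2D dnMCUb and T2D empty vector against that between T2D empty vector and control, across genes, which are not independent replicates. The correlation was -0.128, where 1000 simulated data sets with no effect gave a mean of -0.502, because both differences use the same T2D empty vector libraries. The covariance was -0.000656 against -0.0026 simulated, a difference of 0.00194. The simulation gave every group the same spread for a gene, although the residual SD was 0.0414 in T2D empty vector and 0.0675 in T2D dnMCUb. Only the T2D empty vector libraries are shared, so the simulated -0.502 and -0.0026 lie too far below 0. The difference of 0.00194 is therefore too large. With 1 T2D empty vector library used in each difference, so that none was shared, the covariance was 0.00106 against -2.73e-05 simulated, and the 2 ways of assigning the libraries gave -8.32e-05 and 0.00221. Without library 1 labelled dnMCUb it was 7.72e-05 and without library 2 0.00205, and without control libraries 1 and 2 in turn it was 0.0017 and 0.000427. Of the lists that camera called in both differences, none was called in both with an estimated correlation. Interferon, immediate early and inflammatory genes rose in both differences, and ketone oxidation, glycolysis and sarcomere genes fell in both. Ribosomal protein, heat shock, red cell and atrial lists fell in T2D empty vector against control and rose in the libraries labelled dnMCUb against T2D empty vector, and fatty acid oxidation and autophagy genes rose and then fell. Opposed moves are a pattern that the shared libraries favour with no effect at all.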

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

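The authors' adjusted p and both covariates were added after the data were seen. Among alternatives, the interferon list stayed called in 16 of 16 for T2D dnMCUb against T2D empty vector (medians 0.119 to 0.149) and against control (0.223 to 0.278), and in 15 of 16 for T2D empty vector against control (0.0762 to 0.108), the exception being camera with an estimated correlation (adjusted p = 0.0788). The covariates are counted there by camera at its preset correlation. For T2D dnMCUb against T2D empty vector, the atrial and red cell covariates ended the call with an estimated correlation (adjusted p = 0.251 and 0.654) and by fry (0.0977 and 0.106). For T2D dnMCUb against control, the 9 called genes became 0 with no filter on the mean, with quantile normalization, with each library centred on its median, with only the 2 groups compared, without the trend and with the red cell covariate. The count was 29 at a mean rlog of at least 7, 49 with robust variances, 4 at a difference of at least 0.5, 61 at an adjusted p under 0.10, 104 by the authors' p and 125 with the atrial covariate. All 9 sat at the threshold, and the cause of these moves was not tested. For T2D empty vector against control the 0 became 30 with only the 2 groups, 72 by the authors' p and 12 with the atrial covariate, of which 11 are among the 72. The main fit shares 1 spread over all groups, with a residual SD of 0.0675 in T2D dnMCUb, 0.0379 in control and 0.0414 in T2D empty vector. With only the 2 groups T2D dnMCUb does not enter that spread, and the SE of Mcub went from 0.048 to 0.028. The 0 thus depends on sharing the spread with T2D dnMCUb. For T2D dnMCUb against T2D empty vector it became 9 by the authors' p and 4 (Zbtb16, Dusp1, Irf7 and Fos) with the atrial covariate. Leaving out each library in turn gave 0 to 30, 0 to 14 and 0 to 743 genes for T2D empty vector against control, T2D dnMCUb against T2D empty vector and T2D dnMCUb against control. Lists called were 0, 1 and 1 with an estimated correlation and 1, 1 and 1 by fry in that order, and 13 for the first with the red cell covariate. The covariance of the opposed differences was -0.000656 with shared T2D empty vector libraries, and could not be computed without one of these.

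Medians of called lists turned sign in these cases, and the cause was not tested. With no filter the adipocyte list of T2D empty vector against control was at -0.0217. With the atrial covariate, T2D dnMCUb against T2D empty vector gave 0.0155 for fatty acid oxidation, -0.0165 for fibroblasts, and 0.00154 for conduction, where the test turned and the median did not. With the red cell covariate the values were 0.0120 for nuclear respiratory chain genes in T2D empty vector against control, -0.0511 for epicardium in T2D dnMCUb against T2D empty vector, and -0.0375 for fatty acid oxidation and -0.00566 for red cells in T2D dnMCUb against control. Between T2D dnMCUb and T2D empty vector the atrial and red cell medians also turned, each under the covariate made from its own list. Over omitted libraries, matrix genes ran from -0.0479 to 0.239 in T2D empty vector against control, and atrial genes were at 0.0959 without control library 1. In T2D dnMCUb against T2D empty vector the ranges were -0.172 to 0.0844 for fatty acid oxidation, -0.163 to 0.0303 for the TCA cycle, -0.153 to 0.0429 for sarcomere, -0.0581 to 1.06 for atrial and -0.0781 to 0.326 for fibroblast genes. Without library 1 labelled dnMCUb glycolysis was at 0.000586, and conduction at 0.00545 (from there to 0.140 over omitted libraries), again with the test turned and not the median. In T2D dnMCUb against control the ranges were -0.0653 to 0.208 for fatty acid oxidation, -0.209 to 0.00861 for the respiratory chain and -0.0307 to 0.362 for matrix genes. There fibroblast genes were at -0.0114 without library 1 labelled dnMCUb and ribosomal protein genes at -0.00184 without library 2. A turned sign was counted only for named genes called in the main fit, all of them in T2D dnMCUb against control, and none turned. Genes not called could turn: Mcub in T2D empty vector against control went from 0.0207 to -0.00358 without control library 1. With the red cell covariate it was at -0.0351. With the replicate number as a block, 0, 0 and 0 genes and 19, 19 and 25 lists were called. Equal numbers do not pair the libraries. Differences between replicates 1 and 2 correlated across genes at -0.088 and -0.013 between control and the diabetic groups. Between T2D empty vector and T2D dnMCUb they did so at -0.511, so libraries with unlike numbers resembled each other. Library 1 labelled dnMCUb correlated at 0.99878 with T2D empty vector library 2 and at 0.99766 with library 2 labelled dnMCUb. The latter correlated at 0.99897 with T2D empty vector library 1. The T2D empty vector libraries correlated at 0.99909. The cause was not tested. Depth is unknown, so what it limits cannot be stated.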

Other observations

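The tests of immune cells, of vector injection and of blood were chosen after the results they measure were seen. Several genes that glucocorticoids are known to induce were among the higher genes in the libraries labelled dnMCUb, compared with control by limma. Zbtb16 was higher by 0.79 (SE 0.09), Fkbp5, a co-chaperone of the glucocorticoid receptor, by 0.47 (SE 0.07, adjusted p = 0.0682), Map3k6 by 0.38 (SE 0.05, adjusted p = 0.0523) and Tsc22d3, an anti-inflammatory target of the hormone, by 0.41 (SE 0.09, adjusted p = 0.184). Of 24 genes on a list of such targets written after some values were known, 22 were higher than in control, with a median of 0.162. The 12 list genes whose values had not been seen had a median of 0.0932, with 10 higher (camera adjusted p = 0.00906 over 3 comparisons; adjusted p = 0.538 with an estimated correlation; fry adjusted p = 0.616). The same 12 were called by camera between T2D empty vector and control (median 0.039, adjusted p = 0.0381; adjusted p = 0.538 with an estimated correlation) and not between T2D dnMCUb and T2D empty vector, where the median was 0.0441 (adjusted p = 0.142), with 10 higher in each. All 24 genes, of which 12 had values already seen, were called by camera in both comparisons (medians 0.0877 and 0.0792, adjusted p = 2.52e-06 in each; adjusted p = 0.162 with an estimated correlation). Which of diabetes, vector and cargo the pattern goes with is open. A shared hormone response is a candidate explanation that remains open, because camera called those 12 genes and the other tests did not, and no hormone level is in the labels. Among the 12, Klf9 (0.17), Cebpd (0.18), Nfkbia (0.18) and Cdkn1a (0.14) were highest.

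Interferon genes were higher in the libraries labelled dnMCUb than in T2D empty vector, and in T2D empty vector than in control. Atrial tissue or blood as the whole source is argued against by the size of the median in fits with a covariate. It went from 0.14 to 0.133 (95% bootstrap interval 0.102 to 0.169) with the atrial mean. With the red cell mean it was 0.124 (0.0831 to 0.18). These intervals resample the 34 genes and hold no spread between libraries. Camera at its preset correlation still called the list (adjusted p = 5.5e-24 and 1.55e-09). With an estimated correlation the adjusted p went from 0.0401 to 0.251 and 0.654 and by fry from 0.0153 to 0.0977 and 0.106, so those calls ended, in fits that keep 2 residual degrees of freedom in place of 3. More immune cells remain a candidate source: the interferon median exceeded that of macrophage markers by 0.0636 on rlog (two-sided permutation p = 0.0856, 34 against 16 genes) and by 0.0931 on the authors' folds (p = 0.337). This permutation shuffles genes and holds no spread between libraries. In libraries 1 and 2 labelled dnMCUb the interferon list means were 0.13 and 0.132 and the macrophage means 0.145 and 0.026. Interferon genes thus did not follow macrophage markers within that 1 pair, and lists for neutrophils and lymphocytes were not tested. For T2D empty vector against control, where the median was 0.0931, a response to the vector cannot be told apart from diabetes, since control mice received no vector.

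Red cell genes were higher in the libraries labelled dnMCUb than in T2D empty vector by a median of 0.768 over 7 genes. Blood left in the tissue may account for this: between the control libraries, which share a treatment, the same genes differed by 0.724 (library 1 minus library 2). The difference between libraries was -0.453 in T2D dnMCUb and -0.00329 in T2D empty vector. A true difference in blood content or red cell formation between the groups stays open as untested.

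Matrix genes were higher in library 1 labelled dnMCUb than in library 2 by a median of 0.416, and the atrial genes Myl4 and Myl7 by a mean of 2.78. Atrial tissue in that library is argued against as the whole cause by 1 pair of libraries, the controls. These differed in the same atrial genes by 2.03 and in matrix genes by 0.0404, where 0.304 would be needed in proportion. The 95% bootstrap interval of 0.0134 to 0.0586 resamples the 39 matrix genes and holds no spread between libraries. In T2D empty vector the matrix median was -0.32 beside -0.493 for Myl4 and Myl7. Another region of the heart in the sample, or fibrosis in 1 heart, was not tested.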
